A study of Homo sapiens with 6 samples.

How the data were processed

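Gene expression was measured by RNA sequencing in HTR-8/SVneo cells, an established line derived from human first-trimester trophoblast. The 6 libraries comprised 3 of control cells and 3 of cells given Y15, a small-molecule inhibitor of the autophosphorylation of focal adhesion kinase (FAK, encoded by PTK2), at 3 µM for 24 hours. The labels do not state the vehicle of the controls or whether the replicates were grown separately, so p-values measure only the spread between these samples, which may be technical. Per the labels' protocols, polyadenylated RNA was purified with oligo(dT) beads, second strands were marked with dUTP, adapters carried molecular identifiers, and paired ends were read on a NovaSeq instrument.

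The deposited table holds whole-number counts per Ensembl gene, with no normalization by the authors. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, UMI-tools, StringTie 1.3.4d, DESeq2 and edgeR, with build hg38, but give no role or order for them. The annotation release, the strand setting of the counting, the treatment of the molecular identifiers and the way in which counts were derived are not given in the sources used here. Values of overlapping genes and of genes with near-identical copies, such as histones, hemoglobins, ribosomal proteins and heat shock proteins, are uncertain for that reason. Counting intervals and floors given here cover counting error only.

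The table had 60612 rows, of which 34502 had at least 1 count in the 6 libraries, and none of its sample columns was left out. Total counts per library ranged from 65317588 to 74671290. Gene symbols came from a table of gene names, which gave an entry for 60401 rows and a symbol for 42020. Positions, biotypes, exonic lengths and GC contents came from GENCODE release 29 on GRCh38, which covered 96.34% of the rows. Coordinates are 1-based.

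Low-count genes were removed with edgeR's filterByExpr, which left 20305 genes. Libraries were scaled by TMM factors, and Y15 was compared with control by edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) with group as the only term. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called changed at an adjusted p under 0.05. A second count took called genes with a fitted log2 fold change of at least 1 in either direction. Levels are CPM (counts scaled to a common library total with the TMM factors), given as mean ± SD with n = 3 per group, and log2 fold changes are Y15 minus control with their standard errors (SE). A fold against a group at 0 counts is a lower bound against a floor of 3 counts over the group.

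The 33 gene lists were fixed before the data were examined, as were the tests and the rule for named genes. They were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and lists with fewer than 5 tested members would have been left out. Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera uses the 4 residual degrees of freedom of these libraries, which limits how small its p-values can be. Of the list members written, 1200 were matched to a row and 5 were not (BIM, H2AC18, DDX58 and SOD2, the last in 2 lists). The named genes are 10 fixed in advance (PTK2, PTK2B, RAP1A, RAP1B, MMP2, MMP9, HLA-G, MKI67, CDKN1A and CCND1), the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM, a symbol and no overlap between the groups, and up to 4 called members with the smallest adjusted p of each list. Other members are named where 5 or fewer of a list moved one way, where markers of another cell type required it, or to qualify the members named by rule. These were chosen after their values were seen.

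A further 11 lists were written after the counts had been seen and before the lists were tested: secretory genes of the liver, genes of endometrial epithelium, genes of blood myeloid, T and NK, B and erythroid cells, nuclear-encoded subunits of oxidative phosphorylation, genes of mitochondrial transcription and RNA processing, imprinted genes, cytosolic aminoacyl-tRNA synthetases, and genes of collagen hydroxylation and assembly. Their camera p-values were adjusted over those lists.

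The test was checked on 5 simulated data sets with the means and library sizes of these libraries, in which 200 of 20305 genes were changed. It recovered 18.4% of the genes changed 1.25-fold, 57.6% at 1.5-fold, 76.4% at 2-fold and 93.6% at 4-fold, and 9.36% of the calls were unchanged genes. The changed genes were drawn only from those above a minimum mean count, so recovery at low levels was not checked. Far fewer genes were changed there than were called in the real data, so these shares need not carry over. No pair of libraries within a group was the same library counted again (mean chi-square per gene 12.8 to 41.1), and every library was entered as its own replicate, which the counts cannot verify.

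The alternatives planned in advance were other size factors (RLE, upper quartile, library totals), other count filters, DESeq2 1.42.0, limma voom, edgeR with robust estimation, rows with a symbol only, each library left out in turn, and the replicate number as a block. The planned legacy dispersion method turned out to be the default of the installed edgeR and is therefore the fit described above. Fits without the legacy method, with a per-library offset for gene length and GC content (lowess span 0.3), and with only genes averaging at least 1 CPM in each group were added after the data were seen.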

Results

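RNA from HTR-8/SVneo trophoblast cells was sequenced in 3 control libraries and 3 libraries of cells given the FAK inhibitor Y15 at 3 µM for 24 hours. The libraries held 65317588 to 74671290 counts each, and 20305 genes passed the filter on low counts. The series asks how FAK acts on trophoblast invasion and proliferation, with the Rap1 pathway as the proposed route and preeclampsia as the disease context. The comparison addresses which transcripts differ between the Y15 and the control libraries. FAK phosphorylation is not measured by these libraries.

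The Y15 libraries held more mRNA of hypoxia and glycolysis genes, of p53 targets and of the amino acid and unfolded protein stress programme. They held less mRNA of mitosis genes, of sterol and fatty acid synthesis genes, of several matrix proteins and of all 13 mitochondrial protein-coding genes. Of the gene lists behind these groups, all called by camera with a preset correlation, only hypoxia and glycolysis stayed called with an estimated one. Summed liver transcripts were higher in every Y15 library than in any control, and summed blood cell transcripts were lower. A library batch shared by each group cannot be told apart from Y15, and the differences given here may include it. CDKN1A, which encodes the cell cycle inhibitor p21, rose 3.38-fold from 99.1 ± 4.76 to 335 ± 52.1 CPM, and the proliferation marker MKI67 fell from 525 ± 14 to 261 ± 29.5 CPM. NDRG1, a hypoxia-responsive gene, rose 9.52-fold from 35.3 ± 1.46 to 336 ± 51.5 CPM. PTK2 itself was measured at 207 ± 3.65 CPM in controls and 233 ± 17.5 CPM in Y15 and was not called (log2 fold change 0.17 ± 0.06 SE, edgeR adjusted p = 0.058). Neither list of Rap1 pathway genes was called by camera for a shift in one direction.

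In all, edgeR's quasi-likelihood test called 6528 of the 20305 genes (32.1%), with 3476 higher and 3052 lower in Y15. A change of at least 2-fold was fitted for 1263 of them, 507 higher and 756 lower. The 2 groups did not overlap in 99.0% of the called genes and in 47.0% of all tested genes, against 10% by chance for 3 libraries against 3. The first principal component of log CPM held 48.6% of the variance and separated the groups, and the second, with 15.4%, set control replicate 1 apart from the other libraries. The count of changes of at least 2-fold depended on the filter: it was 786 among genes with at least 1 CPM in 3 libraries, and 492 among genes averaging at least 1 CPM in each group, a filter chosen after the data were seen.

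**Figure D1:**
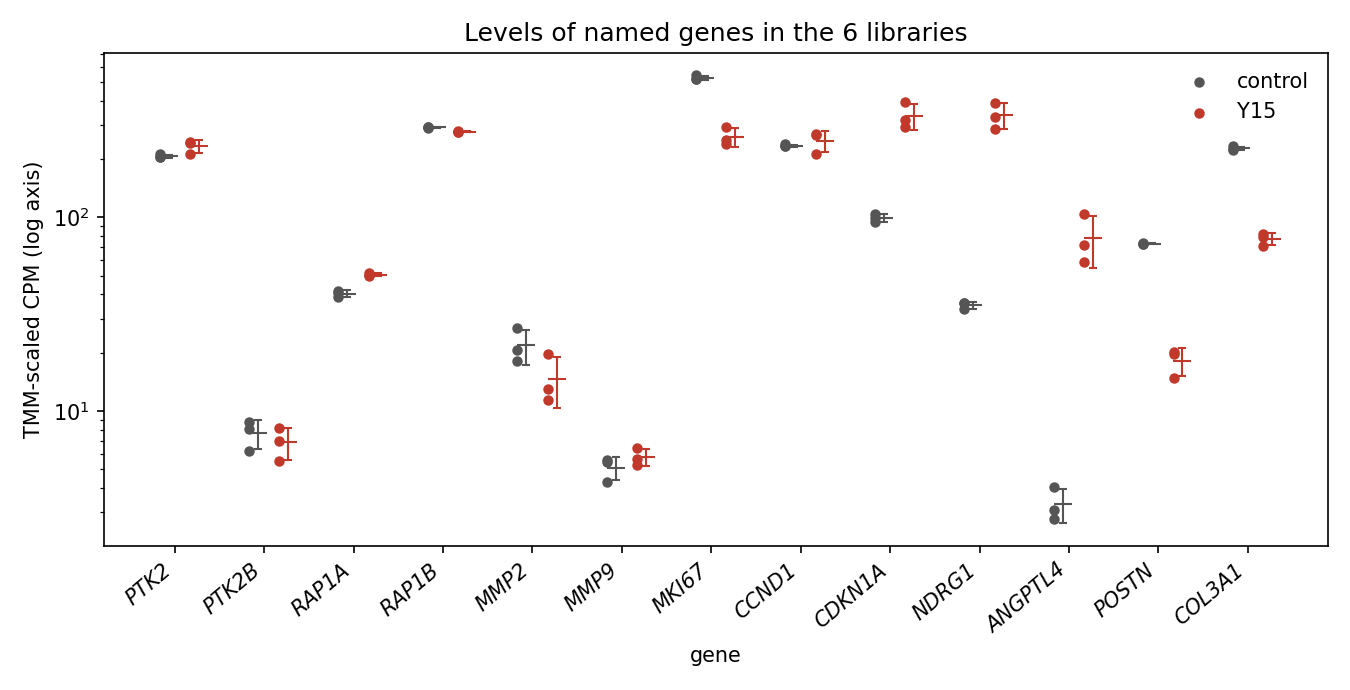
TMM-scaled CPM on a log axis of 13 genes in the 3 control libraries (grey points) and the 3 Y15 libraries (red points), with the mean and SD of each group beside the points. NDRG1, ANGPTL4 and CDKN1A lie higher in all 3 Y15 libraries, MKI67, POSTN and COL3A1 lie lower, and the groups lie close together for PTK2B, RAP1B, MMP9 and CCND1.

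The gene of the kinase that Y15 targets and its paralogue were not called, and other genes of focal adhesions moved in both directions. PTK2 (ENSG00000169398, GRCh38 chromosome 8, 140657900 to 141002216, minus strand) was higher by a fitted 1.12-fold (95% interval 1.035 to 1.217). Its paralogue PTK2B was at 7.69 ± 1.3 CPM in controls and 6.89 ± 1.31 CPM in Y15 (adjusted p = 0.579). Of 43 tested genes of focal adhesions and FAK signalling, 16 fell and 4 rose (18 and 7 adjusted over the list alone). The falls included the adaptor TNS3 (173 ± 6.17 to 81.1 ± 5.27 CPM), the caveolar protein CAV1 (158 ± 6.61 to 71.0 ± 8.70 CPM) and the actin crosslinker FLNA (1103 ± 45.7 to 726 ± 97.9 CPM). The genes that rose were SRC, a kinase that binds phosphorylated FAK (118 ± 3.30 to 176 ± 17.6 CPM), and FYN, PARVB and GIT1. Camera called the list lower (median log2 fold change −0.08, adjusted p = 0.00627). The call was lost with an estimated correlation (adjusted p = 0.287) and with an offset for gene length and GC content chosen after the data were seen (adjusted p = 0.0581). PTK2 was called higher with library totals only (adjusted p = 0.0424), DESeq2 (0.0428), robust edgeR (0.0461), edgeR without the legacy method (0.048), the length and GC offset (0.00155) and without Y15 replicate 1 (0.00807).

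Integrins, the matrix receptors that signal through FAK, moved in both directions. Of 23 tested subunits, 4 rose and 8 fell, with the same counts adjusted over the list alone, and the list was not called (adjusted p = 0.557). ITGA5, the alpha chain of the fibronectin receptor, rose from 199 ± 4.55 to 296 ± 26.8 CPM and ITGB3 from 15.8 ± 0.45 to 30.8 ± 1.87 CPM, and ITGB5 and ITGA6 also rose. ITGA4 fell from 57.1 ± 1.75 to 37.6 ± 1.94 CPM. The falls also took in the leukocyte integrins ITGAL, ITGAM, ITGB2 and ITGB7, and leukocyte transcripts of other kinds were higher in the control libraries as well.

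Single genes of the Rap1 switch were called, but camera found no shared direction for the list. RAP1A (chromosome 1, 111542218 to 111716691), 1 of the pair of genes for the small GTPase Rap1, rose from 40.4 ± 1.60 to 50.7 ± 1.11 CPM (log2 fold change 0.33 ± 0.06 SE, edgeR adjusted p = 0.00292). RAP1B, the more abundant of the pair, was at 292 ± 2.13 CPM in controls and 276 ± 1.70 CPM in Y15 (adjusted p = 0.184). Of 48 tested Rap1 regulators and effectors, 9 rose and 11 fell, with the same counts adjusted over the list alone. Calls were about as common among all tested protein-coding genes (5860 of 14955). SIPA1L2, of a family of Rap GTPase-activating proteins, fell from 30.6 ± 0.80 to 13.3 ± 1.82 CPM and the scaffold MAGI1 from 26.1 ± 1.55 to 15.3 ± 1.40 CPM, while RALGDS, an effector of Ras-family GTPases, rose from 37.6 ± 1.35 to 57.8 ± 1.64 CPM. The list had a median log2 fold change of −0.01 and a camera adjusted p of 0.852. With the length and GC offset RAP1B turned to a call in the other direction (log2 fold change 0.15, adjusted p = 0.0306).

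The ligands, receptors and adenylyl cyclases upstream of Rap1 also divided. Of 65 tested, 17 rose and 15 fell (21 and 18 adjusted over the list alone), and the list was not called (adjusted p = 0.799). The growth factor receptors IGF1R (353 ± 9.33 to 162 ± 7.61 CPM) and MET (344 ± 10.9 to 203 ± 23.9 CPM) fell. The ligands PGF (14 ± 0.98 to 37.3 ± 2.93 CPM) and VEGFA (62.7 ± 3.98 to 107 ± 8.87 CPM) rose.

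PGF and VEGFA are also among 28 tested angiogenic factors and genes associated with preeclampsia, of which 6 rose and 8 fell (7 and 8 adjusted over the list alone). In this list NRP1, a VEGF co-receptor, fell from 159 ± 3.75 to 79.6 ± 2.28 CPM and TGFB1 rose from 87.0 ± 2.78 to 125 ± 7.17 CPM. The list was not called (adjusted p = 0.764).

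Among invasion-related genes, matrix proteins fell more often than they rose. Of 47 tested, 19 fell and 7 rose (20 and 8 adjusted over the list alone), with a median log2 fold change of −0.17 (camera adjusted p = 0.000184). The call was lost with an estimated correlation (adjusted p = 0.51). COL3A1, a fibrillar collagen (chromosome 2, 188974320 to 189012746), fell from 227 ± 5.00 to 77.4 ± 5.66 CPM, the matricellular protein POSTN from 73.2 ± 0.66 to 18.2 ± 2.92 CPM and THBS1 from 226 ± 3.54 to 84.8 ± 11.1 CPM. LOX, which crosslinks collagen, rose from 37.6 ± 2.63 to 104 ± 13.2 CPM.

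Proteases and their inhibitors divided, with 10 of 36 tested genes higher and 6 lower (10 and 7 adjusted over the list alone) and no call for the list (adjusted p = 0.764). SERPINE1, which inhibits plasminogen activators, rose from 73.5 ± 4.25 to 250 ± 33.7 CPM, and its target PLAU, the urokinase, fell from 266 ± 15.8 to 136 ± 10.0 CPM. The membrane protease MMP16 fell from 73.1 ± 2.62 to 33.2 ± 3.18 CPM and the inhibitor TIMP1 rose from 54.0 ± 2.91 to 83.9 ± 4.68 CPM. The gelatinase MMP2 was at 21.8 ± 4.51 CPM in controls and 14.7 ± 4.33 CPM in Y15 (log2 fold change −0.57 ± 0.21 SE, edgeR adjusted p = 0.0594), and MMP9 was at 5.11 ± 0.69 and 5.78 ± 0.59 CPM (adjusted p = 0.473). MMP2 lay close to the threshold: it was called lower without Y15 replicate 3 (adjusted p = 0.00352) and under 8 further settings (adjusted p = 0.0102 to 0.0441).

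Extravillous and villous trophoblast markers moved in both directions. HLA-G, the marker of extravillous trophoblast, had 6 counts in 1 control library and 0 in the other 5, and was not tested. Of 17 tested extravillous markers, 7 fell and 3 rose (8 and 3 adjusted over the list alone), and the list was not called (adjusted p = 0.154). PAPPA fell from 27.2 ± 2.45 to 10.5 ± 2.77 CPM, ADAM12 from 13.6 ± 0.69 to 6.02 ± 0.89 CPM and PLAC8 from 10.2 ± 0.41 to 4.65 ± 0.37 CPM, while ITGA5, NOTCH1 and MCAM rose. Of 12 tested villous cytotrophoblast markers, PEG10 (log2 fold change −0.90), TFAP2A (62.6 ± 2.05 to 29.8 ± 7.51 CPM), EGFR and GATA2 fell, and SPINT1, TFAP2C, ITGA6 and KRT7 rose (5 and 4 adjusted over the list alone), with no call for the list (adjusted p = 0.216).

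Only 10 of 25 syncytiotrophoblast markers could be tested, and 5 of these rose and 1 fell, also when adjusted over the list alone. They were GDF15 (41.6 ± 6.11 to 82.1 ± 7.05 CPM), SLC1A5 (303 ± 20.2 to 487 ± 46.6 CPM), CGB7 (1.75 ± 0.13 to 4.07 ± 0.17 CPM), KISS1 and TFPI2, with CGA lower. GDF15 is also a p53 target and SLC1A5 a glutamine transporter of wide expression. Camera called the list higher (adjusted p = 0.00627), and the call was lost with an estimated correlation (adjusted p = 0.155) and without Y15 replicate 3 (adjusted p = 0.0672).

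Genes of mitosis and of DNA replication fell more often than they rose. Of 50 tested genes of G2/M and mitosis, 31 fell and 4 rose (32 and 5 adjusted over the list alone), with a median log2 fold change of −0.28 (camera adjusted p = 4.28e-13, and adjusted p = 0.181 with an estimated correlation). MKI67 (chromosome 10, 128096659 to 128126385) fell to 0.498 of its control level (95% interval 0.450 to 0.550). The spindle protein ASPM fell from 271 ± 4.79 to 117 ± 8.18 CPM and the kinetochore protein CENPF from 410 ± 16.4 to 208 ± 20 CPM. AURKB, PTTG1, UBE2C and MYBL2 rose. Of 50 genes of DNA replication and the G1/S transition, 21 fell and 8 rose (25 and 8 adjusted over the list alone), among the falls the replicative helicase subunit MCM5 (181 ± 7.60 to 114 ± 6.56 CPM) and UHRF1 (189 ± 9.93 to 120 ± 7.43 CPM). That call (median −0.13, adjusted p = 0.00627) was lost with an estimated correlation (adjusted p = 0.59) and without Y15 replicate 3 (adjusted p = 0.058). CCND1, the cyclin of early G1, was at 235 ± 2.96 CPM in controls and 248 ± 32 CPM in Y15 (adjusted p = 0.508), and was called higher only without Y15 replicate 1 among the settings run (adjusted p = 0.018).

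Replication-dependent histone genes, whose mRNAs lack a poly(A) tail, fell in 12 of 31 tested cases and rose in none, also when adjusted over the list alone. H2AC6 fell from 4.68 ± 0.38 to 1.41 ± 0.30 CPM and H2BC12 from 4.25 ± 0.50 to 1.83 ± 0.25 CPM. The list's median log2 fold change was −1.21 (camera adjusted p = 0.00099), with an adjusted p of 0.155 at an estimated correlation and of 0.0849 among genes averaging at least 1 CPM in each group. The nuclear noncoding RNA MALAT1 fell from 271 ± 26.5 to 70.6 ± 38 CPM.

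Targets of the tumour suppressor p53 rose almost throughout, with 27 of 29 tested genes higher and none lower, also when adjusted over the list alone. The median log2 fold change was 0.67 (camera adjusted p = 7.17e-24, and adjusted p = 0.107 with an estimated correlation). Beside CDKN1A (chromosome 6, 36676460 to 36687339), the antiproliferative gene BTG2 rose from 28.4 ± 0.94 to 92.2 ± 20.2 CPM, the stress sensor SESN2 from 38.3 ± 2.99 to 87.1 ± 11.4 CPM and the BH3-only gene PMAIP1 from 49.9 ± 0.79 to 87.6 ± 6.34 CPM. Other members moved less: MDM2 rose by 0.37 and CCNG1 by 0.25 on the log2 scale, and BBC3 and SPATA18 were not called. SESN2 is also in the ATF4 and unfolded protein response list, and p53 activity itself was not measured.

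Among 36 apoptosis regulators 10 rose and 5 fell (12 and 6 adjusted over the list alone). The rises took in the pore-forming BAK1 (30.0 ± 1.98 to 60.3 ± 4.76 CPM) and the death receptor TNFRSF10B (156 ± 3.46 to 247 ± 16.4 CPM), but also BCL2A1, which opposes apoptosis (0.13 ± 0.02 to 1.56 ± 0.41 CPM). The more abundant BCL2L2 (27.15 ± 0.66 to 45.2 ± 5.01 CPM) and MCL1 (366 ± 13.9 to 406 ± 17.6 CPM), which also oppose apoptosis, rose as well. BOK, BMF, CASP2, BIRC3 and TNFRSF1A fell, the first 3 of which promote apoptosis. The call for the list (median 0.10, adjusted p = 0.0293) was lost with an estimated correlation (adjusted p = 0.161), without control replicate 2 (adjusted p = 0.0675), and under 5 further settings (adjusted p = 0.0514 to 0.121).

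Genes of hypoxia and glycolysis rose in 32 of 42 cases and fell in 4 (33 and 4 adjusted over the list alone), with a median log2 fold change of 0.55. This was the only list called both with the preset correlation (camera adjusted p = 2.24e-33) and with an estimated one (adjusted p = 0.0226). ANGPTL4, an inhibitor of lipoprotein lipase, rose from 3.30 ± 0.66 to 78.2 ± 23.3 CPM, the glycolytic enzyme ENO2 from 116 ± 5.34 to 267 ± 9.61 CPM and the collagen prolyl hydroxylase subunit P4HA2 from 65.6 ± 2.33 to 133 ± 6.91 CPM. NDRG1 lies on chromosome 8 from 133237171 to 133302022. ADM, EGLN1, PLOD2 and PKM fell, and of these the first 3 are known hypoxia-induced genes.

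The ATF4 and unfolded protein response list had 31 of 42 genes higher and none lower (33 and 1 adjusted over the list alone), with a median log2 fold change of 0.67 (camera adjusted p = 5.1e-29, and adjusted p = 0.107 with an estimated correlation). CHAC1, which degrades glutathione, rose from 26.1 ± 2.62 to 69.9 ± 1.60 CPM, the phosphatase regulator PPP1R15A from 133 ± 2.29 to 302 ± 29.1 CPM, the mitochondrial folate enzyme MTHFD2 from 341 ± 7.01 to 675 ± 59.4 CPM and CEBPG from 110 ± 2.48 to 192 ± 11.1 CPM. The chaperone gene HSPA5 had a log2 fold change of 0.33 and was not called.

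Sterol and fatty acid synthesis genes under SREBP control fell in 19 of 33 cases and rose in none (19 and 1 adjusted over the list alone), with a median log2 fold change of −0.31 (camera adjusted p = 3.12e-09, and adjusted p = 0.112 with an estimated correlation). SCD, the stearoyl-CoA desaturase (chromosome 10, 100347124 to 100364834), fell from 701 ± 9.98 to 239 ± 27.8 CPM. The regulators SREBF1 (136 ± 6.78 to 66.3 ± 6.71 CPM) and SREBF2 (211 ± 1.73 to 141 ± 9.72 CPM) and the enzyme HMGCS1 (107 ± 7.04 to 64.9 ± 4.13 CPM) fell with it.

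All 13 mitochondrially encoded mRNAs fell, also when adjusted over the list alone, with a median log2 fold change of −0.84 (camera adjusted p = 1.42e-30, and adjusted p = 0.107 with an estimated correlation). MT-CO1, a subunit of cytochrome c oxidase (mitochondrial chromosome, 5904 to 7445), fell from 10294 ± 341 to 4229 ± 204 CPM, MT-ATP8 from 1807 ± 62.2 to 732 ± 70.5 CPM, MT-ATP6 from 4486 ± 226 to 1957 ± 176 CPM and MT-CO3 from 3925 ± 141 to 1740 ± 163 CPM. The mitochondrial tRNAs MT-TL2, MT-TE and MT-TH were among the 10 largest falls of genes averaging at least 5 CPM. The rRNAs moved the other way: MT-RNR1 rose from 580 ± 44.2 to 1162 ± 314 CPM and MT-RNR2 from 6622 ± 292 to 9276 ± 573 CPM.

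**Figure D2:**
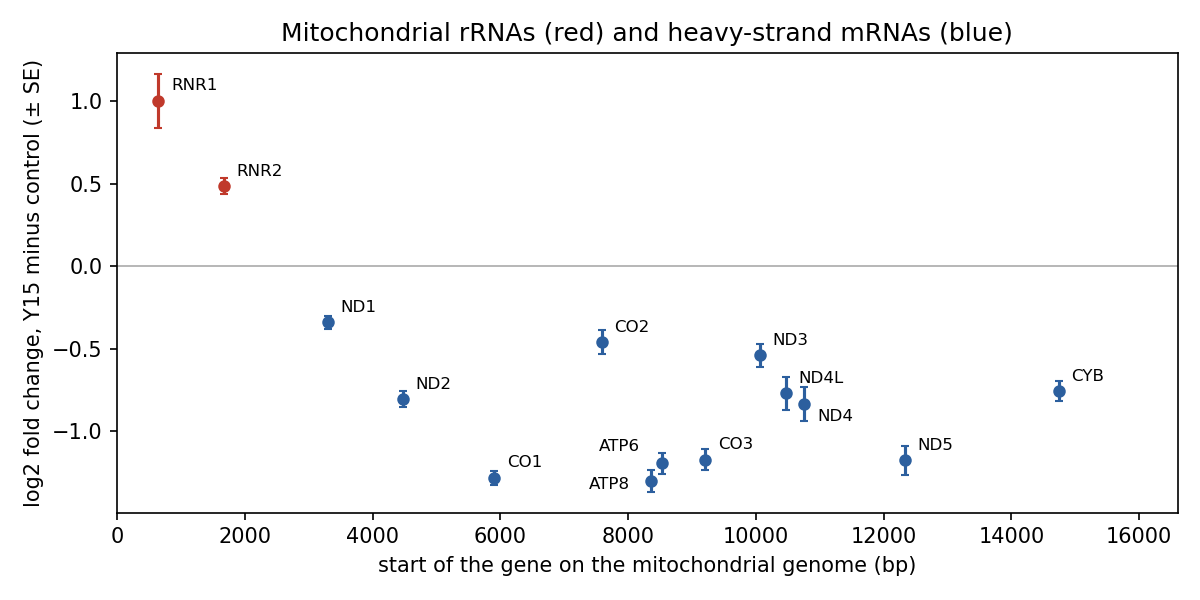
Log2 fold change of Y15 minus control (± SE) of the 2 mitochondrial rRNAs (red) and the 12 mRNAs encoded on the heavy strand (blue), against the start of each gene on the mitochondrial genome in bp. Both rRNAs lie above 0 and all 12 mRNAs below it.

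Cytosolic ribosomal protein genes rose in 60 of 75 cases and fell in none (62 and 0 adjusted over the list alone), with a median log2 fold change of 0.31 (camera adjusted p = 3.66e-21, and adjusted p = 0.181 with an estimated correlation). RPL28 rose from 371 ± 7.73 to 626 ± 8.73 CPM and RPLP0 from 1501 ± 26.4 to 2062 ± 38.3 CPM. Log2 fold changes fell with exonic length across 11375 protein-coding genes (Spearman's rho −0.28, across genes, which are not independent replicates), and their median ran from 0.16 among the shortest genes to −0.11 among the longest.

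Genes of autophagy and the lysosome rose in 21 of 35 cases and fell in none (22 and 1 adjusted over the list alone; median 0.19, camera adjusted p = 0.000926, and adjusted p = 0.181 with an estimated correlation). Examples were GABARAPL1 (28.3 ± 1.58 to 46.5 ± 2.74 CPM), which takes part in autophagosome formation, and the transcription factor TFE3 (48.3 ± 2.26 to 64.7 ± 3.62 CPM). Of 37 NRF2 and oxidative stress genes, 17 rose and 2 fell (20 and 2 adjusted over the list alone; median 0.22, camera adjusted p = 0.000645). AKR1C1 rose from 0.56 ± 0.05 to 5.14 ± 0.89 CPM, the glutathione peroxidase GPX1 from 97.7 ± 4.35 to 149 ± 6.09 CPM and the ferritin chain FTL from 867 ± 13.2 to 1144 ± 49.7 CPM, while UGDH and PRDX1 fell. That call was lost with an estimated correlation (adjusted p = 0.155) and among genes averaging at least 1 CPM in each group (adjusted p = 0.0771). Heat shock and metallothionein genes divided into 7 rises and 7 falls among 24 (8 and 7 adjusted over the list alone; adjusted p = 0.817), with the chaperone HSPA8 down from 1419 ± 44.5 to 774 ± 160 CPM. The metallothionein MT1G had 0 counts in the controls and was at least 45.7-fold higher in Y15.

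Targets of the mechanosensitive factors YAP and TAZ fell more often than they rose. Of 29 YAP/TAZ targets, 15 fell and 5 rose (15 and 6 adjusted over the list alone), with a median log2 fold change of −0.28 (camera adjusted p = 0.0225). PTPN14 fell from 236 ± 7.09 to 156 ± 7.19 CPM and AJUBA from 107 ± 4.13 to 70.4 ± 3.42 CPM, whereas SERPINE1, GADD45A (110 ± 8.64 to 201 ± 15.5 CPM), IGFBP3, FOXF2 and WWC1 rose. The call was lost with an estimated correlation (adjusted p = 0.585), without Y15 replicate 1 (adjusted p = 0.0768) and without Y15 replicate 2 (adjusted p = 0.115). Genes of the SRF pathway and the actin cytoskeleton divided into 14 rises and 16 falls among 49 (15 and 20 adjusted over the list alone; adjusted p = 0.238), with RHOA up from 610 ± 6.65 to 765 ± 32.5 CPM and RHOB down from 254 ± 13 to 168 ± 12.6 CPM. Without Y15 replicate 3 that list was called lower (adjusted p = 0.0254).

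ERK-responsive and immediate early genes were lower in 15 and higher in 10 of 44 cases (16 and 10 adjusted over the list alone; adjusted p = 0.122), with IER2 (133 ± 10.0 to 56.1 ± 2.93 CPM) and EGR1 (178 ± 23.4 to 92.0 ± 4.55 CPM) among the falls. The length and GC offset made it a call for lower expression (adjusted p = 0.00885). NF-κB and inflammatory genes divided into 11 rises and 7 falls among 34 (12 and 9 adjusted over the list alone; adjusted p = 0.328), with IL1B up from 16.4 ± 1.63 to 50.8 ± 2.49 CPM and CXCL1 down from 27.1 ± 4.64 to 11.1 ± 0.81 CPM. Interferon response genes rose in 13 and fell in 5 of 40 cases (16 and 5 adjusted over the list alone; adjusted p = 0.297), and the falls were OAS3 (91.9 ± 1.57 to 63.3 ± 6.44 CPM), STAT2, DDX60, STAT1 and IFIT5. Mesenchymal genes rose and fell in 7 cases each of 26 (8 and 7 adjusted over the list alone; adjusted p = 0.799), with SMAD3 down from 324 ± 5.91 to 219 ± 18.9 CPM.

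**Figure D3:**
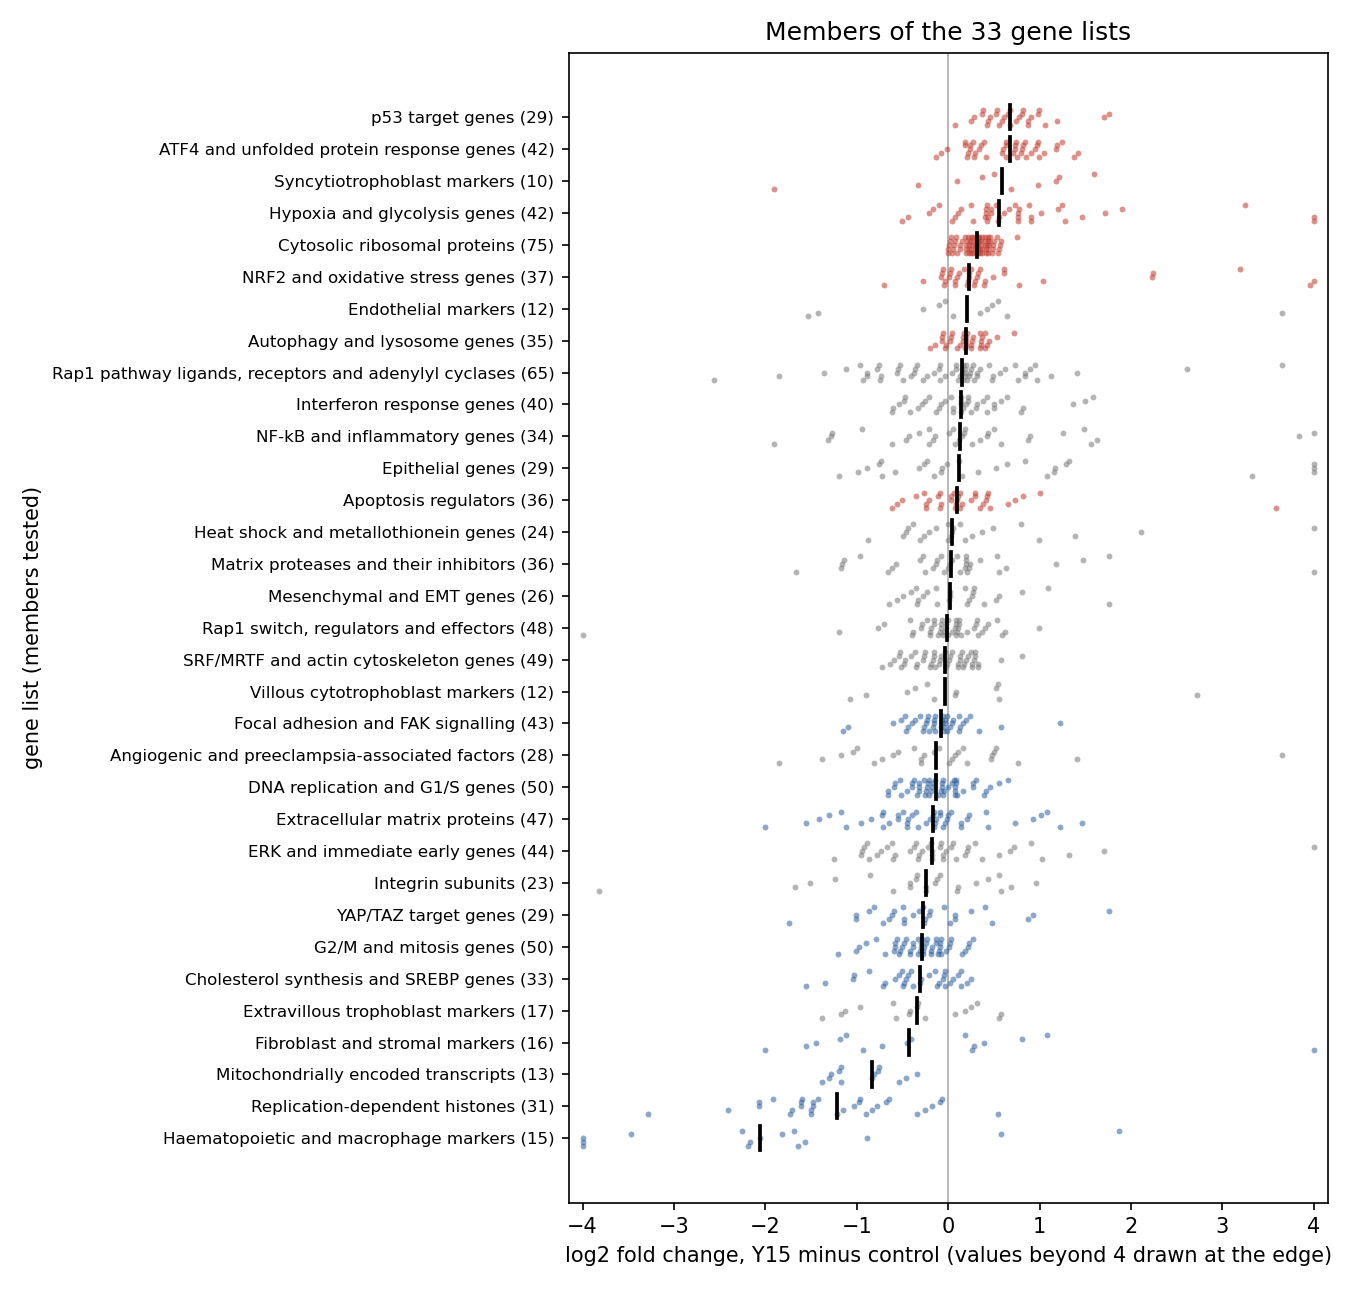
Log2 fold changes of Y15 minus control of the tested members (points) of the 33 gene lists, with each list's median (black bar). Lists called higher by camera at the preset correlation are red, lists called lower are blue and the others are grey, and p53 targets and ATF4 genes have the highest medians (0.67 each).

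With the preset correlation camera called 18 of the 33 lists, 8 higher and 10 lower. Splits of the libraries that mix the treatments still gave 7 to 15 called lists, so a call at this setting does not need the true grouping. With an estimated correlation 1 list was called, and fry, which tests whether a list's genes move on balance one way, called 19.

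Markers of cell types other than trophoblast differed between the groups. Of 15 tested haematopoietic markers, 10 fell and only CD68, a lysosomal protein of macrophages and other cells, rose (11 and 1 adjusted over the list alone). The leukocyte antigen PTPRC was at 7.39 ± 3.34 CPM in controls and 0.37 ± 0.16 CPM in Y15, and LYZ at 15.4 ± 9.16 and 4.36 ± 1.08 CPM. S100A9, the largest fall among genes averaging at least 5 CPM without overlap, was at 9.90 ± 6.73 CPM in controls and 0.17 ± 0.30 CPM in Y15 (0, 0 and 36 counts in the 3 libraries), and its call was lost with limma voom (adjusted p = 0.104) and robust edgeR (adjusted p = 0.0578). The haematopoietic list's call (median −2.06, adjusted p = 0.0164) was lost with an estimated correlation (adjusted p = 0.59), without control replicate 1 (adjusted p = 0.171), Y15 replicate 1 (0.115) or Y15 replicate 3 (0.105), and among genes with at least 1 CPM in 3 libraries (0.608).

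Of 16 tested fibroblast markers, 8 fell and 3 rose (8 and 4 adjusted over the list alone), the falls led by COL3A1, POSTN and COL1A1 (1436 ± 47.8 to 868 ± 60.4 CPM). THY1 and ACTA2 rose, and DLK1 had 0 counts in the controls and was at least 53.6-fold higher in Y15. The median log2 fold change was −0.43, and camera called the list lower (adjusted p = 0.000199), a call lost with an estimated correlation (adjusted p = 0.112) and with limma voom (adjusted p = 0.057). Of 12 endothelial markers, TIE1 (21.4 ± 0.66 to 29.8 ± 1.93 CPM), EGFL7 and KDR rose and none fell, with the same counts adjusted over the list alone and no call for the list (adjusted p = 0.461). KDR was at most 0.51 ± 0.10 CPM, and its call was lost without any 1 of control replicates 1 and 3 and the 3 Y15 replicates (adjusted p = 0.0643 to 0.0707).

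Epithelial genes rose in 7 and fell in 10 of 29 cases (9 and 10 adjusted over the list alone), with no call (adjusted p = 0.799). The list's median was 0.12 while camera's direction was lower. The abundant keratins KRT8 (1072 ± 36.3 to 644 ± 90.4 CPM) and KRT18 (870 ± 23.1 to 582 ± 58.1 CPM) fell. The rises included CDH1 (0.04 ± 0.08 to 1.10 ± 0.32 CPM) and KRT19 (0.12 ± 0.15 to 2.77 ± 0.51 CPM), which are also expressed in endometrial epithelium.

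The largest rises among genes averaging at least 5 CPM were of secretory genes of the liver. ALB, which encodes serum albumin, and A2M had 0 counts in all 3 control libraries and 26.0 ± 11.3 and 14.6 ± 2.93 CPM in Y15, at least 1790-fold and 1000-fold higher. AHSG had 3 counts in the controls, a ratio of 1257 (95% counting interval 430 to 6096), and TF went from 0.12 ± 0.10 to 17 ± 6.06 CPM. SERPINA1 rose from 3.78 ± 0.62 to 21.4 ± 6.64 CPM and IGF2 from 2.62 ± 0.69 to 15.4 ± 4.86 CPM. Over 25 tested liver genes the summed level was 18.6 to 19.6 CPM in control libraries and 94.6 to 182 CPM in Y15 libraries, and over 36 tested blood cell genes it was 43.8 to 115 CPM in control libraries and 15.8 to 25.7 CPM in Y15 libraries.

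**Figure D4:**
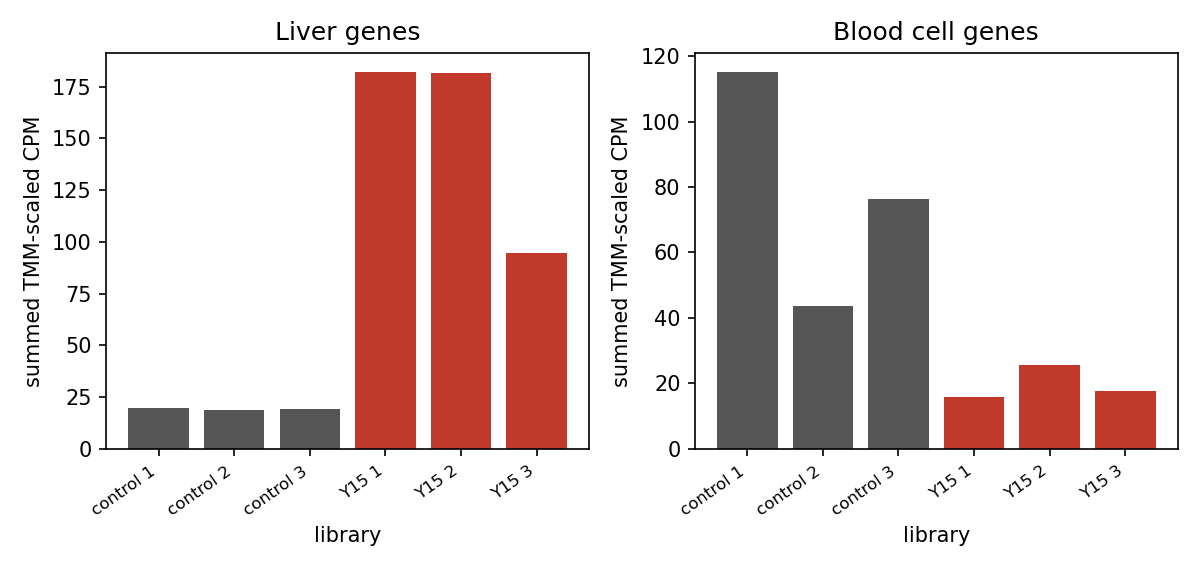
Summed TMM-scaled CPM per library of 25 tested liver genes (left) and of 36 tested blood cell genes (right), with control libraries in grey and Y15 libraries in red. The liver genes lie between 94.6 and 182 CPM in the Y15 libraries and between 18.6 and 19.6 CPM in the controls, and the blood genes lie higher in each control library than in any Y15 library.

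The remaining genes among the 10 largest rises were TOMM6 (3.20 ± 1.98 to 17.4 ± 6.37 CPM), whose call was lost with robust edgeR (adjusted p = 0.0519), and the imprinted noncoding RNA H19 (44.6 ± 3.79 to 200 ± 18.4 CPM). The remaining large falls were MIR503HG (10.3 ± 1.26 to 2.31 ± 1.93 CPM, with 97, 78 and 311 counts in the Y15 libraries and a log2 fold change of −3.11 without Y15 replicate 3), MRPL53 (14.3 ± 2.13 to 3.25 ± 0.47 CPM) and VAT1L (8.40 ± 2.04 to 1.93 ± 0.51 CPM).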

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

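The length and GC offset, the filter on 1 CPM in each group, edgeR without the legacy method and the estimated correlation for lists were tried only after the data had been seen, and the other settings were planned. Between 5078 and 7245 genes were called under every setting run, and all genes called both in a setting and in the fit reported had the same direction there. The share of higher genes ran from 48.4% (length and GC offset) to 56.3% (no low count filter), against 53.2%. No scaling moved the median log2 fold change of all genes by more than 0.03. Leaving out 1 library gave 5078 to 6901 genes (2764 to 3631 higher and 2306 to 3270 lower), 1059 to 1397 of at least 2-fold (413 to 546 higher and 646 to 872 lower), and kept 73.9% to 90.9% of the calls. Y15 replicate 3 stood apart: 6901 genes were called without it and 5078 to 5305 without any other library, and its chi-square per gene against the other Y15 libraries was 33.5 and 41.1, against 12.8 to 18 for the other pairs within groups. Leaving out single libraries left 16 to 18 lists called. The filter on 1 CPM in 3 libraries gave 786 genes of at least 2-fold (303 higher, 483 lower) and that on 1 CPM in each group 492 (178 higher, 314 lower), since both test fewer genes of low level. With an estimated correlation 1 list was called. That test also uses only the 4 residual degrees of freedom of these libraries. Calls lost with it need not come from correlated members alone. The replicate numbers did not pair the libraries (correlations of deviations 0.0028, 0.035 and 0.020 for equal numbers, each below 0.1, although each control correlated best with its own number only for replicates 2 and 3). With the number as a block 6120 genes were called (3265 higher, 2855 lower), 1146 of at least 2-fold (468 and 678), and 18 lists.

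Lists that were not called turned direction in camera in 12 cases, and none was called either way. For heat shock genes the medians were −0.019 (1 CPM in 3 libraries), −0.021 (1 CPM in each group), 0.035 (block), −0.059 (length and GC offset) and 0.055 (without Y15 replicate 3; 0.0092 to 0.055 without single libraries). For the Rap1 switch they were 0.00028 (no filter), 0.029 (length and GC offset) and 0.010 (without control replicate 2; −0.0074 to 0.013 without single libraries), for the other Rap1 list 0.11 (without Y15 replicate 3), and for epithelial genes 0.16 (no filter), 0.087 and 0.13 (without control replicates 2 and 3; 0.052 to 0.19 without single libraries). RAP1B turned to 0.15 and CCND1 to −0.024 with the length and GC offset. The cause of these turns was not tested. Of the other named-gene values in all settings, 16 gained and 9 lost a call, and 2690 kept theirs.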

Other observations

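The tests of the patterns on liver and blood transcripts, of S phase, of mitochondrial RNA as a whole and of order on the heavy strand were chosen after the values had been seen, as were all the lists below. Also after the values were seen, a missed p stopped counting against an order along the heavy strand, and 4 RNAs were held too few to decide on tailless RNA. The bounds first set would have excluded the former and supported the latter. The bound of the S phase test was moved from −0.5 to −0.1 after its value was seen and then set back, and with −0.1 that explanation would have been excluded.

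Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, rose in 14 of 20 cases and fell in none, with a median log2 fold change of 0.35 (camera adjusted p = 2.43e-10, and adjusted p = 0.133 with an estimated correlation). YARS1 rose from 134 ± 7.55 to 285 ± 35.5 CPM, MARS1 from 236 ± 10.4 to 464 ± 52.8 CPM and SARS1 from 126 ± 7.54 to 239 ± 21.9 CPM, and 5 of the 20 are also in a list fixed in advance. Imprinted genes rose in 9 and fell in 2 of 16 cases (median 0.33, adjusted p = 0.00675, and adjusted p = 0.194 with an estimated correlation). Beside H19, MEG3 rose from 5.24 ± 0.56 to 17.3 ± 9.13 CPM and SNRPN from 29.1 ± 3.87 to 53 ± 1.79 CPM, whereas MEST fell from 537 ± 13.8 to 190 ± 15.4 CPM together with PEG10. Of the 9 rises, those of IGF2, DLK1 and PEG3 resemble the transcripts of other tissues: IGF2 had 1375, 1296 and 681 counts in the Y15 libraries, lower in replicate 3 like the liver genes, and DLK1 and PEG3 had 0 and 3 counts over the controls.

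Genes of collagen hydroxylation and assembly rose in 8 and fell in 2 of 15 cases (median 0.14, adjusted p = 5.6e-05, and adjusted p = 0.247 with an estimated correlation), while the collagens COL1A1 and COL3A1 fell. P4HA1 rose from 75.3 ± 2.54 to 139 ± 12.8 CPM and PLOD1 from 138 ± 2.53 to 217 ± 12.9 CPM, and LOXL1 and PLOD2 fell. The genes of mitochondrial transcription and RNA processing mostly stayed without a call: 2 of 21 rose (TFB1M and SLIRP) and 1 fell (TFAM, 186 ± 1.40 to 162 ± 3.28 CPM; adjusted p of the list 0.867).

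The 6 libraries have only 10 splits into 3 and 3, too few for a share under 0.05. The split by treatment gave 6528 genes, 1263 of at least 2-fold and 18 lists, and only 1 split, itself, gave as many of each. The other splits gave 0 genes, 0 genes of at least 2-fold and 7 to 15 lists. Each of them mixes the treatments within its groups, which widens the spread there. The 0 genes were therefore to be expected and lend no weight to the 6528. Lists were called at the preset correlation without the true grouping.

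Transcripts of other tissues differed between the groups: liver genes rose in 20 and fell in 1 of 25 cases (median log2 fold change 5.65, adjusted p = 2.8e-26, and 0.133 with an estimated correlation; 4 of the 25 reach 1 CPM in controls), and genes of endometrial epithelium rose in 14 and fell in 2 of 18 (4.65, 2.43e-10 and 0.133; 5 of 18 reach 1 CPM in controls and 6 are in other lists), while myeloid genes fell in 13 of 14 (−4.36, 1.4e-08 and 0.225), T and NK cell genes in 4 of 10 (−2.40, 0.00931 and 0.308), B cell genes in 5 of 9 with 1 higher (−2, 0.0137 and 0.247) and the 3 erythroid genes in all cases (−2.19, too few for camera). The tables argue against the rises of hypoxia, p53 and ATF4 genes arriving with liver RNA: the excess over the control mean in Y15 replicate 3, relative to replicates 1 and 2, had a median log2 ratio of −0.19 over their 88 risen members (quartiles −0.65 to 0.11), above the quartiles of −1.35 to −0.83 of 18 liver genes. A single outside source of liver RNA stays open, since the range between quartiles of the liver genes' ratio, 0.463, was narrower than the 0.638 of 247 other risen genes of like level, but not beyond chance (1-sided permutation p = 0.136). A library batch shared by each group cannot be told apart from Y15. Of 36 blood genes, 27 had all Y15 libraries below all controls, and the groups' summed liver and blood levels did not overlap. Single genes departed from this: IGHG1 had 31, 29 and 13 counts in controls and 65, 363 and 53 in Y15. PAEP, an endometrial gene, had 34, 39 and 739 counts in the Y15 libraries. Expression of the genes of other tissues by the treated cells themselves was not tested.

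Several RNAs were lower in Y15 that lack a poly(A) tail (12 of 31 histone genes and 15 of 22 mitochondrial tRNAs) or stay in the nucleus (MALAT1 and NEAT1), and the medians of 47 snoRNAs (−0.60, quartiles −1.33 to −0.20) and 22 miRNAs (−0.55, quartiles −0.93 to −0.18) were also below 0, although only 1 snoRNA was called at their low levels. Gene length and GC content as the whole cause are argued against by the histone list, whose median moved from −1.21 to −1.37 with the offset for both and stayed called. Fewer cells in S phase as the whole cause was tested on the mitochondrial tRNAs, which are not tied to S phase. They cannot tell why the histone genes fell. Of these tRNAs, 15 of 22 fell and none rose (median −1.17, quartiles −1.69 to −0.34). The rule set for this test left it undecided, since their upper quartile did not pass the bound of −0.5. A lower carry-through of tailless RNA in the Y15 libraries may account for the falls of tailless RNA and stays open. The mitochondrial rRNAs rose (log2 fold change 1.00 for MT-RNR1 and 0.49 for MT-RNR2), but how the beads captured them was not measured. The mitochondrial mRNAs fell along with the tRNAs (median −0.84), so the fall of the tRNAs need not come from a missing tail. The median of 4 small RNAs was −1.13, but 4 are too few to decide. Of these, RN7SL1 and RN7SL2 fell, and RN7SK and SCARNA22, both under 0.3 CPM, were not called. An effect of Y15 on nuclear RNA was not tested, although NEAT1 (438 ± 22.4 to 242 ± 67.0 CPM) fell with MALAT1.

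Mitochondrial mRNAs fell while the rRNAs rose. A loss of all mitochondrial RNA alike is excluded only for the RNA captured in these libraries. There MT-RNR1 rose by 1.00 on the log2 scale (edgeR adjusted p = 0.00137), and MT-RNR2 rose by 0.49. The RNA was purified with oligo(dT) beads, and capture of rRNA was not measured. Levels in the cells therefore cannot be told from these values. A joint fall of nuclear and mitochondrial genes of oxidative phosphorylation is excluded by the 74 nuclear-encoded subunits, of which 30 rose and 3 fell (median 0.12, quartiles −0.01 to 0.22; camera adjusted p = 0.00569, and 0.28 with an estimated correlation). A fall that grows along the heavy-strand transcript could not be decided, with Spearman's rho of −0.41 over 14 genes (permutation p = 0.146) and −0.06 over the 12 mRNAs (permutation p = 0.851).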
